A study of Arabidopsis thaliana with 9 samples.

How the data were processed

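The deposited tables hold, per the file headers, an exon count and an intron count for each of 37869 loci in each of 9 libraries. Per the submitters' processing notes the reads were aligned with STAR, whose version was not given. The genome build, the annotation, the counting program, its strandedness and its rule for assigning a count to introns were not given in the sources used here. Per the labels' protocols the RNA was poly(A)-selected from 12-day-old seedlings grown in long days, with 3 biological replicates per genotype. Exon counts per library ran from 20733294 to 27022497. The authors' counts were taken as raw read counts, which their whole-number values allow.

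Locus names, biotypes and overlaps came from the TAIR10.1 annotation, in which 37573 loci were found and 296 were not. Overlap with other genes was judged on that annotation, which may not be the one counted. The planned analysis of primary miRNA loci was not run, and these loci were not analysed here.

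Exon counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR's robust quasi-likelihood model with one mean per genotype, which left 22631 genes. The contrasts were each allele against Col-0, the mean of both alleles against Col-0, and pp4r3a-2 against pp4r3a-1. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, from two-sided tests over all genes. Each SE was taken as the absolute log2 change divided by the square root of edgeR's F statistic. It can fall below counting error where a group has few counts. SEs and floors cover at most counting error and the spread of the 3 replicates. A floor of 3 counts stands in for a group without counts.

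Of 22 gene lists written before the data were examined, 21 had loci in the tables, and those with at least 5 tested genes were tested with camera. Its preset correlation was 0.01 and the prior count of log CPM was 2. An estimated correlation and fry were the alternatives. The named genes follow a fixed rule with a mean of at least 1 CPM: 10 up and 10 down in both alleles, with every mutant library beyond every Col-0 library, 5 up and 5 down per allele and between alleles, and up to 4 per list by smallest p in the mean contrast. Genes named besides these were chosen after their values were seen, and the text says so.

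Intron counts were modelled with exon counts in edgeR as a ratio for 11133 genes with at least 90 intron counts over the 9 libraries. This step and its naming rule were set after the files were examined. The rule took genes with at least 10 intron counts in each Col-0 library, a mean exon level of at least 10 CPM and no overlapping gene, 6 per direction. Its alternatives were genes without overlap, at least 450 intron counts, limma on the log2 ratio with a pseudocount of 0.5, and that ratio centred on each library's median.

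The alternatives set beforehand were RLE, library size or upper quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 20), an adjusted p under 0.01, a 2-fold minimum, DESeq2, voom, leaving out organelle genes, fitting only the groups compared, the replicate number as a block, and leaving out each library. Agreement of the alleles through the noise of shared Col-0 libraries was simulated 20 times for genes and 10 times for introns. All libraries, Col-0 included, were drawn from Col-0 means, so an offset of the real Col-0 libraries was not simulated.

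The steps were tested on simulated data. With 200 changed genes per draw, edgeR recovered 78.1% of 1.5-fold, 88.4% of 2-fold and 98.6% of 4-fold changes, and 141 of 1900 calls were false (7.42%), which is above the nominal 5%. The intron step, run on 1 draw, recovered 63.3% of 2-fold changes, with 4 of 109 calls false (3.67%). Its simulated intron counts were given the spread of the exon counts. In both simulations far fewer genes were changed than were called in the data, so these rates may not hold for the data. In the list test the 1 shifted list was called and 0 of the others.

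R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.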

Results

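Polyadenylated RNA was sequenced from 12-day-old Arabidopsis thaliana seedlings of 3 genotypes. These were the wild-type accession Col-0 and the mutants pp4r3a-1 and pp4r3a-2, which carry separate alleles of PP4R3A (AT3G06670), a regulatory subunit of the serine/threonine protein phosphatase 4 (PP4). Each genotype had 3 biological replicates. Exon counts summed to 25328467, 25642851 and 23343990 in the Col-0 libraries, 27022497, 24779843 and 22735573 in pp4r3a-1, and 23879676, 25802186 and 20733294 in pp4r3a-2. In these libraries 3 counts corresponded to 0.111 to 0.145 counts per 1e6 counts (CPM). After filtering, 22631 genes were tested. The first principal component, holding 72.7% of the variance, and the second, holding 17.7%, separated the 3 genotypes, and the biological coefficient of variation was 0.0388. In pp4r3a-2 replicate 3, chloroplast-encoded genes took 0.962% of the exon counts and ribosomal RNA genes 0.503%, against 0.427% to 0.558% and 0.113% to 0.208% in the other 8 libraries.

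The PP4R3A transcript was lower in both mutants. It stood at 80.6 ± 1.37 CPM in Col-0, 62.3 ± 2.74 CPM in pp4r3a-1 and 18.4 ± 0.262 CPM in pp4r3a-2 (mean ± SD, n = 3 each). Its log2 fold change was -0.37 (SE 0.041) in pp4r3a-1, with an edgeR adjusted p of 3.44e-10, and -2.13 (SE 0.049) in pp4r3a-2, with an edgeR adjusted p of 2.75e-30. The alleles differed by -1.76 (SE 0.050; edgeR adjusted p 1.42e-26). Among the other PP4 genes, the catalytic subunit gene PPX2 (AT5G55260) fell by 0.30 and 0.28 on the log2 scale in pp4r3a-1 and pp4r3a-2 (edgeR adjusted p 0.000303 and 0.000831). Its paralog PPX1 (AT4G26720) had log2 values of -0.07 and 0.07, and neither passed the test (edgeR adjusted p 0.204 and 0.226). The regulatory subunit gene PP4R2L (AT5G17070) rose by 0.22 in pp4r3a-2 (edgeR adjusted p 0.00474) and had 0.08 in pp4r3a-1 (edgeR adjusted p 0.271). The counts were summed over all exons of a gene, so they do not show which part of the PP4R3A transcript remained, and PPX1 overlaps AT4G26710 on the opposite strand.

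**Figure D1:**
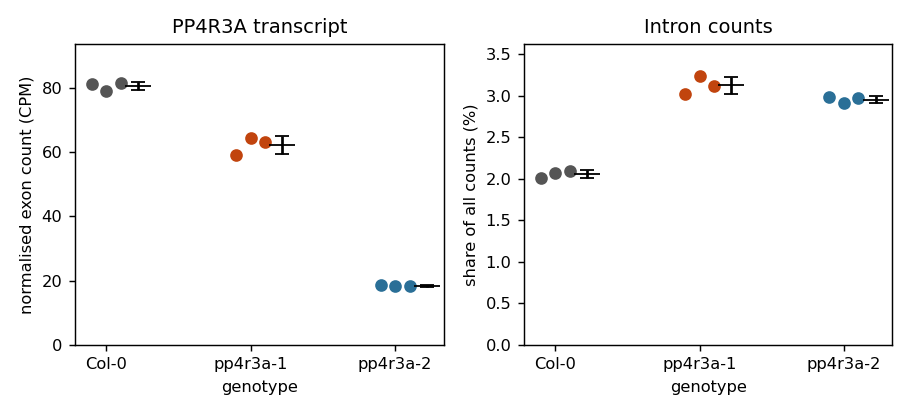
PP4R3A transcript level (left, normalised exon count in CPM) and intron share of all counts (right, in percent) by genotype; points are libraries, and bars are the mean ± SD of 3 libraries. PP4R3A stood at 80.6 CPM in Col-0, 62.3 CPM in pp4r3a-1 and 18.4 CPM in pp4r3a-2, while introns took 2.06%, 3.13% and 2.95% of the counts.

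The next question was which transcripts changed in the mutants, taken as the mean of the alleles against Col-0. A change in a single allele can move this mean, and the genes called in each allele are counted further below. Genes of anthocyanin synthesis rose furthest as a group. PAP1 (AT1G56650), the MYB transcription factor that activates this pathway, went from 0.12 ± 0.0054 CPM in Col-0, which is 3 counts per library, to 39.9 ± 1.46 CPM in pp4r3a-1 and 10.6 ± 1.19 CPM in pp4r3a-2 (n = 3 each). DFR (AT5G42800), encoding dihydroflavonol reductase, rose by 6.30 (SE 0.056) and 5.44 (SE 0.057) on the log2 scale in pp4r3a-1 and pp4r3a-2. LDOX (AT4G22880), encoding anthocyanidin synthase, rose by 6.19 and 5.27, and TT19 (AT5G17220), a glutathione transferase needed for flavonoid accumulation in the vacuole, by 6.03 and 5.18. The plastid glucose-6-phosphate translocator GPT2 (AT1G61800) rose by 8.44 and 6.07, and the granule-bound starch synthase GBSS1 (AT1G32900) by 6.72 and 5.40, from 2.46 CPM in Col-0 to 260 and 104 CPM.

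The other genes named by the fixed rule for the largest rises were NUDT24 (AT5G19470), a nudix hydrolase, with 8.18 and 5.71, and a set with near-zero counts in Col-0. AT2G15780 had no count in any Col-0 library and was at least 22.3-fold higher in pp4r3a-1 and at least 3.72-fold higher in pp4r3a-2, against a floor of 3 counts per Col-0 library. The pseudogene AT2G35570 stood at 0.0819 CPM in Col-0 and at 4.84 and 7.09 CPM in the mutants, and AT1G30170 at 0.0661, 3.56 and 4.09 CPM. Among the largest falls, AT1G31690, a copper amine oxidase gene, dropped from 35.6 ± 1.28 CPM to 1.11 ± 0.0949 and 0.405 ± 0.0163 CPM. AT2G33830, of the dormancy and auxin-associated family, went from 961 CPM to 39.8 and 111 CPM, and the dark-inducible gene SEN1 (AT4G35770) from 225 CPM to 7.90 and 46.9 CPM. JMJD5 (AT3G20810), a jumonji-domain gene linked to the circadian clock, fell by 3.48 and 4.06, the methylesterase gene MES18 (AT5G58310) had values of -6.05 and -3.94, and the MADS-box gene AGL14 (AT4G11880) fell by 3.25 and 3.87. AT2G05160 fell by 3.51 in each allele, AT5G00650 by 4.05 and 3.14, and the pair MRD1 (AT1G53480) and AT1G07887 had values of -2.103 and -2.12 in pp4r3a-1 and -4.996 and -5.01 in pp4r3a-2. MRD1 and AT1G07887 overlap on opposite strands, as TT19, AT1G30170 and MES18 do with other genes, and AT2G35570 overlaps AT2G35555 on the same strand, so their counts may be shared. In either allele, edgeR's adjusted p was at most 3.05e-30 for DFR, LDOX, TT19, GPT2, GBSS1 and NUDT24, 1.405e-25 for PAP1 and 2.54e-17 for the genes named as falling.

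In all, 8375 genes were higher and 8531 lower in the mean of both alleles, which is 37.0% and 37.7% of the genes tested with edgeR's quasi-likelihood test. Of these, 1921 were at least 2-fold higher and 1350 at least 2-fold lower. Each allele called alone shared 6438 higher and 6472 lower genes with the other, of which 1426 and 859 were at least 2-fold changed in both. Independent lists of these sizes would share 2926.5 and 2923.1 genes. With all libraries simulated from Col-0 means without any change, the alleles shared 0.15 in each direction on average over 20 simulations. Few calls were bound to result there, so this value does not show what an offset of the real Col-0 libraries would add. Across genes, which are not independent replicates, the log2 fold changes of the alleles had a correlation of 0.851 (simulated 0.501) and a covariance of 0.657 (simulated 0.0138), and 83.6% had the same sign (simulated 66.6%). With 3 Col-0 libraries the controls cannot be divided into groups of at least 2, so part of the excess may come from the shared controls. Of the shared genes, 58.1% of the higher and 59.4% of the lower ones changed more in pp4r3a-1.

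**Figure D2:**
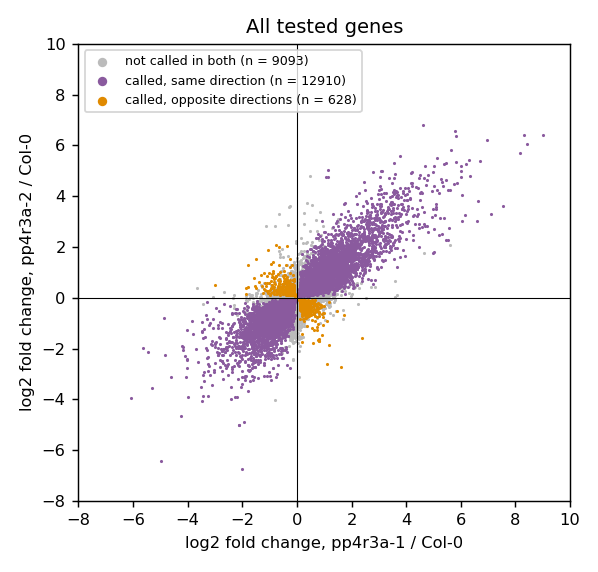
Log2 fold change in pp4r3a-2 (vertical) against that in pp4r3a-1 (horizontal), both over Col-0, for the 22631 genes tested; each point is a gene, coloured by whether both alleles called it in the same direction, in opposite directions, or not both. Most points called in both lie along the diagonal, 6438 higher and 6472 lower, and 628 lie in the opposite quadrants.

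Of 19 fixed gene lists large enough to test, 12 were called in the mean contrast by camera with its preset correlation, each toward higher expression, and 6 remained called with an estimated correlation. All 14 flavonoid and anthocyanin genes rose, with a median log2 change of 4.201 (camera adjusted p 9.94e-10), UF3GT (AT5G54060), an anthocyanin glycosyltransferase, by 5.39 (SE 0.087). Of 16 aliphatic glucosinolate genes 15 rose and 1 fell (median 1.02; camera adjusted p 1.21e-06), with CYP79F1 (AT1G16410) up by 2.45, the transporter gene BAT5 (AT4G12030) by 1.51, MAM1 (AT5G23010) by 1.1995 and CYP83A1 (AT4G13770) by 1.002. In the DNA damage list 15 of 17 rose and none fell (median 1.39; camera adjusted p 2.65e-06). NAC044 (AT3G01600), a NAC factor of the damage response, rose by 3.83 (SE 0.094), GMI1 (AT5G24280), linked to recombination, by 2.86, the ribonucleotide reductase gene TSO2 (AT3G27060) by 2.17 and PARP2 (AT4G02390) by 1.87. Of 15 phosphate starvation genes 13 rose and 1 fell (median 0.79; camera adjusted p 2.48e-05), with the phosphatase genes PS2 (AT1G73010) and PAP17 (AT3G17790) up by 4.07 and 2.37, the phosphate sensor gene SPX1 (AT5G20150) by 2.63 and the sulfolipid synthase gene SQD2 (AT5G01220) by 0.79.

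In the salicylic acid and defence list 18 of 26 rose and 3 fell (median 0.63; camera adjusted p 0.000587). The camalexin synthesis genes CYP71A13 (AT2G30770) and PAD3 (AT3G26830) rose by 3.38 and 3.12 and WRKY18 (AT4G31800) by 2.03, while ACD6 (AT4G14400), a membrane protein acting in salicylic acid signalling, fell by 2.36. The marker gene PR1 (AT2G14610), chosen after its values were seen, rose by 4.68 (SE 0.14). Heat shock genes numbered 14 higher and 2 lower of 16 (median 1.03; camera adjusted p 0.00173), and the alleles differed widely in them, as given below for the direct comparison. These 6 lists kept their call with an estimated correlation, with camera adjusted p of 0.00817 for flavonoids, 0.0111 for glucosinolates and for DNA damage, 0.0226 for phosphate, 0.0242 for salicylic acid and 0.0379 for heat shock.

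A further 6 lists were called with the preset correlation only. Of 20 jasmonate genes 17 rose (median 0.79; camera adjusted p 2.40e-06; adjusted p = 0.0551 with an estimated correlation), with the lipoxygenase genes LOX4 (AT1G72520) and LOX3 (AT1G17420) up by 3.66 and 1.84, VSP2 (AT5G24770) by 1.52 and AOS (AT5G42650) by 1.42. Of 21 genes of abscisic acid, cold and drought response 18 rose and 2 fell (median 1.31; camera adjusted p 2.65e-06; adjusted p = 0.0535 with an estimated correlation). RD29A (AT5G52310) rose by 2.81, RD22 (AT5G25610) by 1.97 and the proline synthesis gene P5CS1 (AT2G39800) by 1.94, while the cold-regulated gene COR15B (AT2G42530) fell by 2.29. Of 9 seed storage and maturation genes 8 rose (median 2.74; camera adjusted p 0.00032; adjusted p = 0.0786 with an estimated correlation), among them the oleosin genes OLEO1 (AT4G25140) and OLEO2 (AT5G40420) by 4.06 and 3.54 and the cruciferin genes CRA1 (AT5G44120) and CRC (AT4G28520) by 3.05 and 2.204. In the cell cycle list 19 of 28 rose and 3 fell (median 0.27; camera adjusted p 0.000617; adjusted p = 0.0786 with an estimated correlation), with the replication licensing genes MCM5, MCM2, MCM3 and MCM7 up by 1.14, 1.05, 0.998 and 0.98. In the auxin list 11 of 17 rose and 1 fell (median 0.46; camera adjusted p 0.00559; adjusted p = 0.0535 with an estimated correlation), with the conjugating enzyme genes GH3.3 and GH3.2 up by 1.31 and 0.85 and the repressor gene IAA3 by 0.55. The repressor gene IAA2 rose in pp4r3a-2 alone, by 1.16, with a value of -0.07 in pp4r3a-1 (edgeR adjusted p 0.263).

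The circadian clock list moved in both directions: 19 of 28 genes rose and 8 fell (median 0.94; camera adjusted p 0.00332; adjusted p = 0.0786 with an estimated correlation). Among the morning-expressed genes, LNK1 (AT5G64170) and LNK2 (AT3G54500) rose by 3.84 (SE 0.061) and 3.32 (SE 0.053), and the evening gene PRR3 (AT5G60100) fell by 2.56 (SE 0.051), while GI (AT1G22770), which peaks late in the day, rose by 1.84 (SE 0.038). Chosen after their values were seen, the morning genes CCA1 (AT2G46830) and LHY (AT1G01060) rose by 5.32 and 3.55, and the evening genes ELF3 (AT2G25930), LUX (AT3G46640) and TOC1 (AT5G61380) fell by 1.23, 1.17 and 0.83. Outside the clock list, 8 genes with a morning or daytime peak had a median log2 change of 2.11 and 5 with an evening or night peak a median of -1.50, a difference of 3.61 (exact two-sided permutation p 0.00777 over 1287 arrangements of these genes, which share libraries and partly regulation, are not independent replicates, and so make this p too small). By allele, the evening median was -1.69 in pp4r3a-1 and -0.62 in pp4r3a-2, and the morning median 1.93 and 2.24. The hour of harvest of each genotype was not given in the sources used here. A difference in that hour would coincide with genotype. It could also move genes outside the clock list whose level varies through the day, among them possibly the clock-linked JMJD5, the dark-inducible SEN1 and other genes named here.

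**Figure D3:**
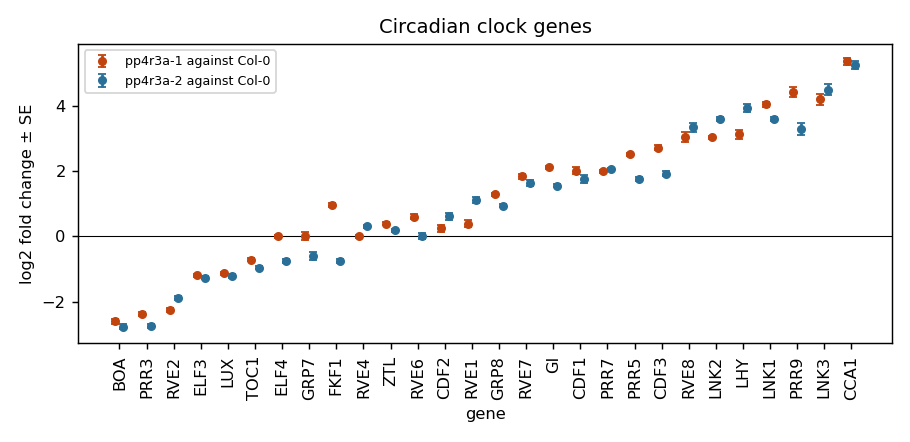
Log2 fold change of 28 circadian clock genes in pp4r3a-1 and pp4r3a-2 against Col-0 (vertical), ordered by the mean of both alleles; points are the fitted value and bars its SE, from 3 libraries per genotype. CCA1 at 5.38 and 5.26 marks the upper end, and PRR3 at -2.38 and -2.74 lies near the lower end.

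The remaining lists were not called in the mean contrast. Nuclear-encoded photosynthesis genes numbered 23 higher and 23 lower of 47 (median -0.03, mean 0.22, camera direction up, camera adjusted p 0.912). The light-harvesting genes LHCB2.1 (AT2G05100), LHCB2.2 (AT2G05070) and LHCB2.3 (AT3G27690) rose by 4.35, 3.90 and 3.09, LHCB2.1 from 92.0 ± 1.298 CPM to 1873 ± 42.3 and 1881 ± 8.45 CPM, while the Rubisco small subunit gene RBCS2B (AT5G38420) fell by 1.49; near-identical copies may share reads in both families. Of 6 senescence genes 4 rose and 1 fell (median 0.83; camera adjusted p 0.0959), SAG29 (AT5G13170) and SAG13 (AT2G29350) by 4.92 and 4.89 and the chlorophyll breakdown gene NYE1 (AT4G22920) by 0.76. Flowering genes numbered 6 higher and 9 lower of 18 (median -0.31; camera adjusted p 0.327), with CO (AT5G15840), MAF2 (AT5G65050) and FLM (AT1G77080) down by 1.64, 0.77 and 0.81. Chosen after their values were seen, the florigen gene FT (AT1G65480) fell by 2.54 (SE 0.26) and the repressor gene FLC (AT5G10140) rose by 0.98 (SE 0.076). Root markers numbered 4 higher and 9 lower of 18 (median -0.19, mean 0.01, camera direction down, camera adjusted p 0.671), with THAS1, WOX5 and PYK10 up by 1.23, 1.38 and 0.17. PRP3 rose in pp4r3a-1 alone, by 1.0004, with a value of -0.08 in pp4r3a-2 (edgeR adjusted p 0.379). The PP4 list, with 1 of 4 genes higher and 2 lower, and the floral organ list of 3 genes were too small to test. In the latter, SHP1 rose in pp4r3a-2 alone, by 0.69 (0.13 in pp4r3a-1, edgeR adjusted p 0.462), and SEP3 fell in pp4r3a-1 alone, with -0.98 (0.23 in pp4r3a-2, edgeR adjusted p 0.139). Adjusted over the list alone, the counts of higher and lower genes in the mean contrast were those over all genes tested, except for miRNA targets with 41 higher and 27 lower. Counts of TSO2, GMI1, CYP71A13, PAP17, P5CS1, COR15B, OLEO1, OLEO2, MCM7, IAA3, LNK1, LNK2, CO, LHCB2.3, PYK10 and SHP1 are uncertain in the same way, because each overlaps another gene.

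**Figure D4:**
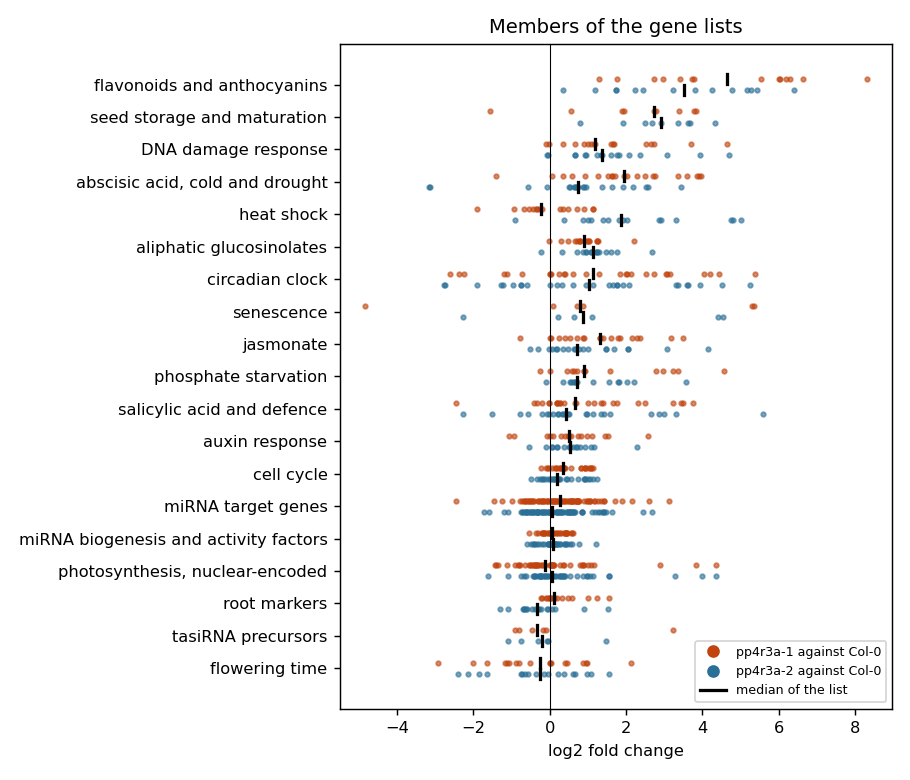
Log2 fold change over Col-0 (horizontal) of the members of the 19 tested gene lists (vertical, ordered by median), in pp4r3a-1 and pp4r3a-2; each point is a gene and each bar the median of its list. Flavonoid genes lie farthest right, with medians of 4.66 and 3.52, and heat shock genes part by allele, with medians of -0.23 and 1.87.

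In pp4r3a-1 against Col-0, which shows this allele alone, 8212 genes were higher and 8174 lower by edgeR's test, 2079 and 1550 of them by at least 2-fold. NATA1 (AT2G39030), an acetyltransferase gene that answers to jasmonate, was among the largest rises with 7.10 (SE 0.14), beside GPT2, PAP1, NUDT24 and AT2G15780. NATA1 had only 5, 6 and 5 counts in the Col-0 libraries, so its SE is likely too small. The noncoding locus AT2G06995 stood at 2.103 CPM in Col-0 and 0.0688 CPM in pp4r3a-1, where it had 0, 3 and 2 counts. The other large falls were MES18, AT1G31690, SEN1 and AT2G33830. MES18 had 3, 4 and 4 counts in pp4r3a-1. Both AT2G06995 and MES18 thus lie near the floor of 3 counts, and the size of their falls is uncertain. Of the 19 lists, 12 were called toward higher expression and 6 with an estimated correlation. Abscisic acid genes numbered 19 higher and 1 lower of 21 (median 1.94; camera adjusted p 1.82e-08, and adjusted p = 0.0333 with an estimated correlation), with RD29A up by 3.97 (SE 0.045) from 37.0 to 581 CPM. All 14 flavonoid genes rose (median 4.66). Heat shock genes split evenly, 5 higher and 5 lower of 16 (median -0.23; camera adjusted p 0.770), HSFA7A (AT3G51910) falling by 1.90. The calls lost had adjusted p = 0.0673 with an estimated correlation for cell cycle (22 higher, 0 lower of 28) and jasmonate (17 and 1 of 20), 0.0729 for clock (19 and 6 of 28) and auxin (11 and 2 of 17), 0.124 for seed genes (7 and 1 of 9) and 0.132 for miRNA targets. Adjusted over the list alone, the counts differed only for photosynthesis, with 18 higher and 24 lower in place of 17 and 24. Signs differed for photosynthesis (median -0.11, mean 0.11, camera direction down) and tasiRNA precursors (median -0.32, mean 0.13, camera direction down).

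In pp4r3a-2 against Col-0, 8065 genes were higher and 8093 lower by edgeR's test, 1913 and 1412 of them by at least 2-fold. Heat shock genes rose in this allele: 15 of 16 were higher and 1 lower (median 1.87; camera adjusted p 8.10e-06, and adjusted p = 0.0102 with an estimated correlation). HSP17.6A (AT5G12030) went from 0.357 ± 0.055 to 11.7 ± 1.01 CPM, HSP17.4 (AT3G46230) from 0.598 ± 0.055 to 16.3 ± 0.536 CPM and HSP70 (AT3G12580) from 20.3 ± 2.08 to 72.1 ± 2.92 CPM (n = 3 each). PRB1 (AT2G14580), encoding a basic pathogenesis-related protein, dropped from 4.43 to 0.144 CPM. The remaining genes at the extremes were those named above for both alleles, PAP1, GPT2, AT2G15780, AT2G35570 and AT1G30170 upward and AT1G31690, MRD1, AT1G07887 and JMJD5 downward. All 14 flavonoid genes and all 9 seed genes rose (medians 3.52 and 2.91). The 12 lists called were again all toward higher expression, and 7 kept the call. The others had adjusted p = 0.155 with an estimated correlation for cell cycle (16 higher, 5 lower of 28), 0.106 for jasmonate (15 and 2 of 20) and for abscisic acid (16 and 3 of 21), 0.141 for clock (18 and 9 of 28) and 0.0780 for seed genes. Adjusted over the list alone, no list count differed.

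The alleles were then compared with each other, to see where pp4r3a-2 differed from pp4r3a-1. Heat shock genes were higher in pp4r3a-2, with 15 of 16 up and none down (median 2.097; camera adjusted p 2.14e-11). HSP17.6C (AT1G53540) was higher by 4.33 (SE 0.18), HSP17.6A by 3.87 (SE 0.15) and HSP17.4 by 3.62 (SE 0.13), the last overlapping the noncoding locus AT3G07365, higher by 3.69, on the opposite strand. In pp4r3a-1 HSP17.6C had only 8, 12 and 8 counts, so its SE is likely too small. Abscisic acid genes were lower, 20 of 21 (median -1.02; camera adjusted p 5.44e-13), with RD29A at -2.33 (SE 0.040), COR15B at -1.77 and P5CS1 at -1.12, and so were all 14 flavonoid genes (median -0.98; camera adjusted p 2.14e-11), with PAP1 at -1.91 (SE 0.065). NATA1 and GolS3 (AT1G09350), a galactinol synthase gene, were lower by log2 values of -3.80 and -3.58. AT2G06895, which overlaps AT2G06905 on the same strand and AT2G06935 on the opposite strand, was lower at -3.28, and the noncoding loci AT2G06995 and AT5G03615 were higher, at 0.0688 and 0.116 CPM in pp4r3a-1 and 1.15 and 2.02 CPM in pp4r3a-2. In pp4r3a-1 AT2G06995 had 0, 3 and 2 counts and AT5G03615 had 5, 3 and 1. Both lie near the floor of 3 counts, so the size of their difference is uncertain.

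By edgeR's test 5484 genes were higher and 5361 lower in pp4r3a-2 than in pp4r3a-1, 515 and 613 of them by at least 2-fold. Against Col-0 the alleles called 628 genes in opposite directions, of 13538 called in both. Among them 7 changed at least 2-fold in each allele, chosen after their values were seen except for the first and second named: the pseudogenes AT1G43590 (1.61 in pp4r3a-1, -2.74 in pp4r3a-2) and AT1G69140 (1.11 and -2.60), AT2G29220 (2.38 and -1.59), AT5G36130 (1.16 and -1.88), AT2G17850 (-1.81 and 1.31), AT4G01490 (-1.04 and 1.86) and the beta-glucanase gene BG3 (AT3G57240; -1.49 and 1.51). Of the 11 lists called, heat shock, abscisic acid and flavonoids kept the call, with adjusted p = 0.00296, 0.0224 and 0.00296 with an estimated correlation. Without pp4r3a-2 replicate 3, their medians were 2.097, -1.02 and -1.004.

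The calls lost between the alleles were photosynthesis, with 37 higher and 1 lower of 47 (median 0.21; camera adjusted p 7.49e-08; adjusted p = 0.304 with an estimated correlation), and root markers, with 13 of 18 lower (median -0.58; camera adjusted p 0.00012; adjusted p = 0.0841 with an estimated correlation), PRP3 being lower by a log2 value of -1.08. They also included glucosinolates (11 higher, 3 lower; adjusted p = 0.0754 with an estimated correlation), miRNA targets (12 higher, 38 lower; 0.112), phosphate (4 and 8; 0.114), cell cycle (1 and 12; 0.228), clock (8 and 15; 0.231) and jasmonate (6 and 12; 0.304). Adjusted over the list alone, the counts that differed were 16 higher and 0 lower for heat shock, 38 and 2 for photosynthesis, 13 and 39 for miRNA targets, 5 and 8 for miRNA factors (5 and 9 over all genes), 1 and 2 for flowering (3 and 3), 7 and 14 for salicylic acid (6 and 14) and 6 and 13 for jasmonate. Signs differed for auxin (median -0.28, mean 0.0003), senescence (median -0.06, mean 0.19) and tasiRNA precursors (median 0.08, mean -0.26), with camera direction down in each.

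The series concerns primary miRNA transcription and processing, so the genes of this pathway were examined as a group. Of 38 genes for miRNA biogenesis and activity 17 rose and 11 fell in the mean of both alleles, by small amounts (median 0.09; camera adjusted p 0.203). The largest evidence was for HST (AT3G05040), the exportin-5 ortholog, and MAC7 (AT2G38770), of the MOS4-associated complex, which rose by 0.60 (SE 0.046) and 0.55 (SE 0.036), for the kinase gene MPK3 (AT3G45640), which rose by 0.66 (SE 0.036), and for MOS2 (AT1G33520), an RNA-binding protein, which fell by 0.52 (SE 0.041). Chosen after their values were seen, the dicing genes differed: DCL1 (AT1G01040) fell by 0.23 (SE 0.040), SE (AT2G27100) rose by 0.42 (SE 0.036) and HYL1 (AT1G09700) did not pass the test (edgeR adjusted p 0.958), while AGO1 (AT1G48410), the main effector of miRNAs, fell by 0.27 (SE 0.032). Of 84 miRNA target genes 41 rose and 26 fell (median 0.23; camera adjusted p 0.0832). In pp4r3a-1 there were 46 higher and 20 lower, which camera called with its preset correlation (adjusted p 0.00781; adjusted p = 0.132 with an estimated correlation), and in pp4r3a-2 there were 36 and 30 (camera adjusted p 0.316).

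Among single targets, the floral repressor gene TOE1 (AT2G28550) rose by 1.67 (SE 0.034), the ATP sulfurylase gene APS1 (AT3G22890) by 1.33 (SE 0.033) and the methyltransferase gene PXMT1 (AT1G66700) by 2.91 (SE 0.075), while the copper/zinc superoxide dismutase gene CSD2 (AT2G28190) fell by 1.41 (SE 0.042). Of 6 tasiRNA precursors 1 rose and 3 fell (median -0.26, mean 0.00051, camera direction down, camera adjusted p 0.327). TAS4 (AT3G25795) rose by 2.36 (SE 0.18), from 0.658 CPM to 6.20 and 1.84 CPM, and TAS1A, TAS1B and TAS1C fell by 0.84, 0.94 and 0.39. MPK3, TAS1B and TAS1C overlap genes on the opposite strand.

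Counts in introns, deposited beside the exon counts, were higher in the mutants. Introns took 2.06 ± 0.0475% of all counts in Col-0, 3.13 ± 0.104% in pp4r3a-1 and 2.95 ± 0.0376% in pp4r3a-2 (mean ± SD, n = 3 each), and all 6 mutant libraries lay above all 3 Col-0 libraries. The mutants exceeded Col-0 by 0.982 percentage points, with an exact two-sided permutation p of 0.0119, the smallest that 84 arrangements allow. Each allele alone, with differences of 1.07 and 0.896 percentage points, reached an exact permutation p of 0.1, the smallest for 3 libraries against 3. Per gene, the intron-to-exon ratio was higher for 8724 of 11133 genes tested and lower for 140 in the mean of both alleles. The median log2 change was 0.93, and 94.1% of the genes had a positive value. Genes entered by intron counts summed over all libraries, so weakly counted genes could enter through high mutant counts. This can raise the median and the share of positive values. With at least 450 intron counts the median was 0.795. The median of 0.93 is 1.91-fold, a larger change than that of the pooled share. Of genes overlapping no other gene, 5705 of 6952 were higher and 35 lower (median 0.99). Of genes whose exon counts changed by under 0.25 on the log2 scale, 3934 of 4868 were higher and 42 lower (median 0.95). Across genes, which are not independent replicates, the ratio and exon changes had a correlation of -0.0539.

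A rule set after the files were examined named the well-counted genes with the largest ratio changes. In UBQ10 (AT4G05320), a polyubiquitin gene, introns held 0.116 ± 0.0115% of the gene's counts in Col-0, 1.01 ± 0.101% in pp4r3a-1 and 0.990 ± 0.0802% in pp4r3a-2, a log2 change of the ratio of 3.11 (SE 0.13) in the mean contrast. The tetraspanin gene TET8 (AT2G23810) went from 0.845% to 12.3% and 5.20%, AT4G19200 from 0.306% to 2.71% and 4.28%, and AT3G49560, AT3G61260 and the tubulin gene TUB5 (AT1G20010) rose by 3.09, 3.09 and 3.04 on the log2 scale. Of the genes with a lower ratio, the same rule named 6. RS31 (AT3G61860), an SR protein gene, went from 21.7 ± 0.885% to 10.5 ± 0.678% and 9.77 ± 1.41%, the RNA helicase gene UAP56a (AT5G11170) from 16.1% to 7.50% and 7.52%, and GRP8 (AT4G39260), a glycine-rich RNA-binding protein gene, from 12.0% to 7.32% and 5.07%. In the ABC transporter gene ABCG40 (AT1G15520) the ratio fell by 4.76 while its exon counts rose by 4.66. The ratios of AT1G54380 and the arginase gene ARGAH2 (AT4G08870) fell by 2.201 and 1.33. Exon counts also rose in ARGAH2, by 2.83, and in GRP8, by 1.12. Summed intron counts of ARGAH2 rose from 40 in Col-0 to 125 and 95, and those of GRP8 went from 2770 to 3902 and 1926. In RS31, UAP56a and AT1G54380 exon counts changed by -0.197, 0.0368 and 0.133. UBQ10 and UAP56a have near-identical copies that may share reads.

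Among the fixed lists, the ratio rose in all 3 PP4 genes tested, the mutated gene PP4R3A by 2.32, PPX2 by 1.41 and PP4R2L by 1.49. In PP4R3A exon counts changed by -1.25, so part of its rise reflects fewer exon counts. Its summed intron counts were 119 in Col-0, 355 in pp4r3a-1 and 162 in pp4r3a-2. The ratio also rose in 27 of 31 miRNA factor genes (median 1.04), with 1 lower. Over all genes 8724 of 11133 were higher and 140 lower (median 0.93), and no test compared the lists with these. Examples chosen after their values were seen were HYL1 by 2.92 (SE 0.45), URT1 by 2.05, KETCH1 by 1.91 and HST by 1.55, while GRP7 fell by 0.44 and DCL1 did not pass the test, at 0.06 (SE 0.16, edgeR adjusted p 0.717). Summed over the 3 Col-0 libraries, intron counts were only 6 for HYL1, 29 for URT1, 80 for KETCH1 and 36 for HST. HYL1 and URT1 thus fell short of the 10 per Col-0 library asked of the well-counted genes. The ratio was higher in 37 of 46 miRNA target genes, 29 of 35 photosynthesis genes, 10 of 19 clock genes with 2 lower, and 1 of 8 flavonoid genes. In pp4r3a-1 it was higher in 8649 genes and lower in 129 (median 0.99), in pp4r3a-2 in 7779 and 136 (median 0.87), and 7377 and 78 genes were shared. Independent lists would share 6043.3 and 1.58. With all libraries simulated from Col-0 means without any change, 0.1 and 0 were shared over 10 simulations, where few calls were bound to result. The covariance of the alleles was 0.469 (simulated 0.0610) with a correlation of 0.893 (simulated 0.488). Part of this excess may come from the shared Col-0 libraries. Between the alleles edgeR called 167 ratios higher and 748 lower in pp4r3a-2 (median -0.11), but limma on the log2 ratio called 4 and 14, and 463 were lower without pp4r3a-2 replicate 2. With each library's ratios centred on their median, limma called 2020 higher and 2464 lower in the mean contrast, relative to that median. These ratios came from an edgeR model of exon and intron counts, and the rule by which the authors assigned reads to introns was not given in the sources used here.

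**Figure D5:**
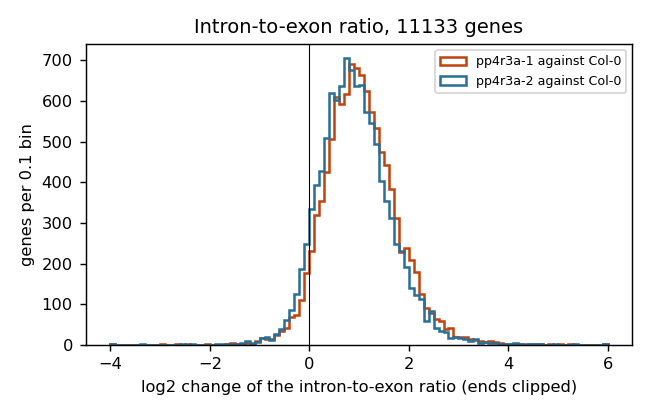
Number of genes (vertical, per 0.1 bin) by log2 change of the intron-to-exon ratio (horizontal, ends clipped) in pp4r3a-1 and pp4r3a-2 against Col-0, for 11133 genes. Both distributions lie right of 0, with medians of 0.99 and 0.87.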

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

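Tests on genomic DNA in the genes that rose and on harvest time were chosen before their results were seen. Those on genomic DNA in all genes, on overlapping neighbours, on separate batches, on pp4r3a-2 replicate 3 and on regrouped libraries were chosen after the patterns were seen.

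Introns took 3.13% of the counts in pp4r3a-1 and 2.95% in pp4r3a-2, a signal in counts on which the sources used here report nothing. Genomic DNA would add intron counts evenly. Over 11044 genes not chosen by their ratio, the added counts per kilobase were at least 3.67 times higher in the most than in the least expressed quartile, in each of 6 mutant libraries. In the 7373 genes whose ratio rose in both alleles the lowest such value was 2.98, which is not counted, since those genes were chosen by that rise. The 11044 genes had passed an intron count minimum over all libraries, mutants included, which can raise the value of the least expressed quartile. Over all 23723 loci with introns, summed per quartile, added counts were 0.00433 to 0.011 CPM per kilobase in the least expressed quartile. In the most expressed quartile they were 1.16 to 1.46, over the 6 mutant libraries. The values of both sets argue against genomic DNA as the whole cause of the signal. Those over all loci also argue against it as the main cause across these loci. Reads from overlapping neighbours are unlikely to explain it, as the median log2 change was 0.992 in genes that overlap none. Separate batches of RNA or library preparation stay possible: same-numbered libraries of Col-0 and a mutant correlated by at most 0.0144, so the numbers do not show how batches ran. An effect of PP4R3A on splicing or on the decay of unspliced RNA stays open as a hypothesis, and none of the tests here addressed it.

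The morning clock genes CCA1 and LHY were higher and the evening genes TOC1, ELF3 and LUX lower in both alleles, while GI, which peaks late in the day, was higher by 1.84 in their mean. Outside the clock list the morning and evening medians differed by 3.61, with HEMA1 at 0.02 in pp4r3a-1 and CAT3 at 0.07 in pp4r3a-2 not passing the test. A later harvest of Col-0 than of the mutants predicts a difference of at least 1, so harvest time may account for part of the pattern, though the rise of GI runs against an afternoon harvest of Col-0. An effect of PP4R3A on the clock could give it as well. The sources used here give no harvest times, and samples taken through a day would be needed to tell these apart.

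Between the alleles, heat shock genes had a median log2 difference of 2.097, abscisic acid, cold and drought genes -1.02 and flavonoid genes -0.98, and 628 genes were called in opposite directions against Col-0; a difference between groups brought these up. The library pp4r3a-2 replicate 3, which has more chloroplast and ribosomal RNA, is not the source for these lists, as the heat shock median was 2.097 without it, and 589 genes were then called in opposite directions, 559 of them the same. Growth or harvest of the alleles in separate batches may be, since same-numbered libraries of the alleles correlated by at most 0.0311 and so do not show how the plants were grown. The lower PP4R3A transcript of pp4r3a-2 could account for the heat shock genes, but flavonoid and abscisic acid genes and 58.1% of shared higher genes changed more in pp4r3a-1, and the counts do not show which part of the transcript remained; a second mutation in either line was not tested.

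Libraries were regrouped in simpler fits than those of the results above, with edgeR on only the libraries compared and as a pair of groups for genes, and limma on the log2 ratio for introns, so the counts differ from those given there. Regrouping gave, for pp4r3a-1 against Col-0, 16222 genes and 8253 intron ratios with the real groups and at most 0 and 0 otherwise; for pp4r3a-2 against Col-0, 16355 and 7254 against 0 and 0; and for pp4r3a-2 against pp4r3a-1, 10349 and 35 against 0 and 0. In each, 1 of 10 splits, the real one, had that many, and 10 splits are too few for a share under 0.05. For the mean of both alleles, 1 of 84 splits reached the 13731 genes of the real groups in these fits and 1 of 84 their 8495 intron ratios. This is the smallest share that 84 splits allow, so chance is unlikely there but not excluded. Every split that mixed libraries of a genotype with others gave 0 genes, so few splits could compete with the real groups. The highest other splits, with 3993 genes and 1 ratio, followed genotype: pp4r3a-1 against the rest gave 3993 and pp4r3a-2 against the rest 2286.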

How the results depend on the processing

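Of the recomputed values of 26 main results, 402 kept their direction and size, 42 moved and 3 reversed. Of 3424 values of 197 single genes and lists, 3401 kept their call or lack of one, 15 lost a call, 7 gained one and 1 reversed. For these, direction was compared only where the main or the alternative setting made a call. A change of sign without any call was counted as kept. The scalings, filters, DESeq2, voom, organelle genes left out and fits to only the groups compared (not possible for the mean of both alleles) moved no gene count more than 1.5-fold. The planned primary miRNA alternatives were not run. All intron alternatives and the genes added later were chosen after the results were seen. Except where construction is named, the cause was not tested.

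By construction, the 2-fold minimum lowered the counts of higher and lower genes to 2079 and 1550 in pp4r3a-1, 1913 and 1412 in pp4r3a-2, 1921 and 1350 in their mean, 515 and 613 between alleles, and 1426 and 859 in both alleles. With an estimated correlation 6 lists stayed called in the mean contrast in place of 12, and with fry 18 of 19 were called. Without overlapping genes, fewer were tested, and intron ratios were higher, lower and at a median of 5678, 27 and 1.05 in pp4r3a-1, 5122, 48 and 0.927 in pp4r3a-2, and 5722, 35 and 0.992 in the mean, with 102 higher between alleles. With at least 450 intron counts these were 2398, 82 and 0.833; 2214, 87 and 0.737; and 2388, 92 and 0.795. limma called 4 higher and 14 lower between alleles. Centring sets each median near 0 by construction, so they reversed to -0.0509, -0.0628 and -0.0532, with 1676 higher and 2003 lower, 1613 and 2011, and 2020 and 2464, and between alleles 5 and 12 with a median of -0.00365; the DCL1 ratio reversed to -0.93.

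Leaving out 1 library gave 7825 to 8277 higher and 7792 to 8219 lower in pp4r3a-1, 7608 to 8204 and 7615 to 8314 in pp4r3a-2, 7936 to 8405 and 8079 to 8600 in the mean, 4861 to 5407 and 4755 to 5364 between alleles, and 463 to 768 lower intron ratios between alleles. PP4R2L, called in the mean contrast, lost its call with library size (adjusted p 0.0609), upper quartile (0.101), DESeq2 (0.0770), and without Col-0 replicate 2 (0.113) or pp4r3a-2 replicate 3 (0.0524), and SEP3 with DESeq2 (0.0552) and without Col-0 replicate 2 (0.0616). Replicate number as a block gave 8346 higher and 8512 lower in the mean and changed no count more than 1.5-fold; same-numbered libraries correlated by -0.0413 to 0.0311, so the numbers do not pair. Depth limits genes near 3 counts, at 0.111 to 0.145 CPM.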

Other observations

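The following counts by gene class of the reference annotation, in the mean of both alleles, were chosen after their values were seen, and no test compared the classes. Of 116 genes classed as ncRNA 10 were higher and 71 lower (median log2 change -0.48), with 9 and 71 in pp4r3a-1 and 13 and 69 in pp4r3a-2. Of 30 snoRNA genes 14 were higher and 3 lower (median 0.38), and of 103 loci without a match in the reference 61 were higher and 3 lower (median 0.64). Long noncoding RNA genes numbered 302 higher and 285 lower of 892. Over all 22631 genes tested, 8375 were higher and 8531 lower.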
